A study of Mus musculus with 30 samples.

How the data were processed

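RNA was sequenced from 30 cultures of mouse C2C12 myotubes, the multinucleated muscle cells that form when the C2C12 myoblast line is differentiated. The 10 groups held 3 libraries each, and the series' design text calls them biological replicates. Per the labels, poly(A) RNA was made into directional MGIEasy libraries and sequenced as paired ends on a DNBSEQ instrument.

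Per the submitters' processing notes, the tools used were FastQC 0.11.9, Trim Galore 0.6.10, STAR 2.7.9a and RSEM 1.3.3, with the genome builds GRCm38 and mm10. The gene annotation and the strand setting of the counting are not given in the sources used here. The deposited table held expected counts per gene, estimated by the authors with RSEM, which divides reads that match several genes among them. The values were not normalized, and 19.4% of them were not whole numbers. Genes with close copies, such as Gstm1 and Gstm2 or the ribosomal protein genes with their pseudogenes, are therefore uncertain. The table held 16025 gene symbols, of which 16021 matched the names in the GENCODE vM21 annotation of GRCm38, which supplied the coordinates.

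Expected counts were rounded to whole numbers. Totals ranged from 22209229 to 30218353 counts per library, so that a count of 3 corresponded to 0.0993 to 0.135 CPM, counts scaled to the library's total. The 30 replicate pairs within groups differed by more than sampling noise, with chi-square values per degree of freedom from 2.46 to 13.7 over genes with enough counts, and no library was merged with another.

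The main test was edgeR 4.0.16 (quasi-likelihood F-test with robust fitting) in R 4.3.3, in a single group model over all 30 libraries with TMM scaling and filterByExpr, which kept 12184 genes. CPM printed for genes were scaled to each library's total over the kept genes times its TMM factor. The common dispersion was 0.00181, a biological coefficient of variation of 4.25%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The errors printed beside log2 fold changes are standard errors worked back from the test: the absolute log2 fold change divided by the square root of F. Comparisons were each treatment against its own baseline, the saponin against the non-saponin fraction with D-galactose, an omnibus test of whether the D-galactose effect differed over the 5 backgrounds, and an omnibus test of differences among the 4 pretreated D-galactose groups.

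The design, the alternatives, 29 gene lists with 612 genes and the rule for named genes were fixed before the data were examined. Of those genes, 13 stood in 2 lists. Lists with at least 5 tested members, 28 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Counts of called members are given over all genes tested and, where stated, adjusted over the list alone. The rule for named genes took genes with adjusted p under 0.05, a mean of at least 5 CPM and all 3 libraries of a group above all 3 of the other. Predicted genes, clone names and symbols with -ps were left out. It named the 10 largest rises and 10 largest falls after D-galactose and the 5 and 5 in each other pairwise comparison. It also took the 6 genes of smallest p in each omnibus test, up to 4 members of each called list and a fixed set of muscle and stress genes. The text summarises some of these genes instead of naming each.

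The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, a fit with only the groups compared and each library left out in turn. Lists were also tested with a correlation estimated per list, with fry, with RLE scaling and with the block. In simulated data for D-galactose against control, with 50 of 12106 genes changed per fold size, the test recovered 68% of the genes changed 1.3-fold, 86% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, and made 10 false calls. No library or gene symbol was left out by hand.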

Results

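Gene expression was measured in C2C12 myotubes that received D-galactose, a sugar used in the laboratory to bring on ageing-like changes, with or without a preparation from Korean Red Ginseng. The preparations were the water extract (RGW), its saponin fraction (SFr), its non-saponin fraction (NSFr) and the purified saponin ginsenoside Rb2. Vehicle control, D-galactose (Dgal), the 4 preparations alone and the 4 preparations followed by D-galactose (RGW_Dgal, SFr_Dgal, NSFr_Dgal, Rb2_Dgal) gave 10 groups of 3 libraries. D-galactose was used at 20 mg/mL for 24 h, the extract and fractions at 100 µg/mL and Rb2 at 20 µM, with 12 h of pretreatment. The first principal component held 36.4% of the variance and set the 6 SFr libraries, with and without D-galactose, apart from the other groups. Mitochondrially encoded genes took 0.727% to 1.69% of the counts, with 0.908% ± 0.211 in control and 1.49% ± 0.183 in Dgal (SD, n = 3). Without D-galactose the share was 1.29% ± 0.0367 after RGW, 1.22% ± 0.120 after SFr, 1.18% ± 0.0433 after NSFr and 0.858% ± 0.129 after Rb2. In SFr_Dgal it was 1.21% ± 0.224.

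**Figure D1:**
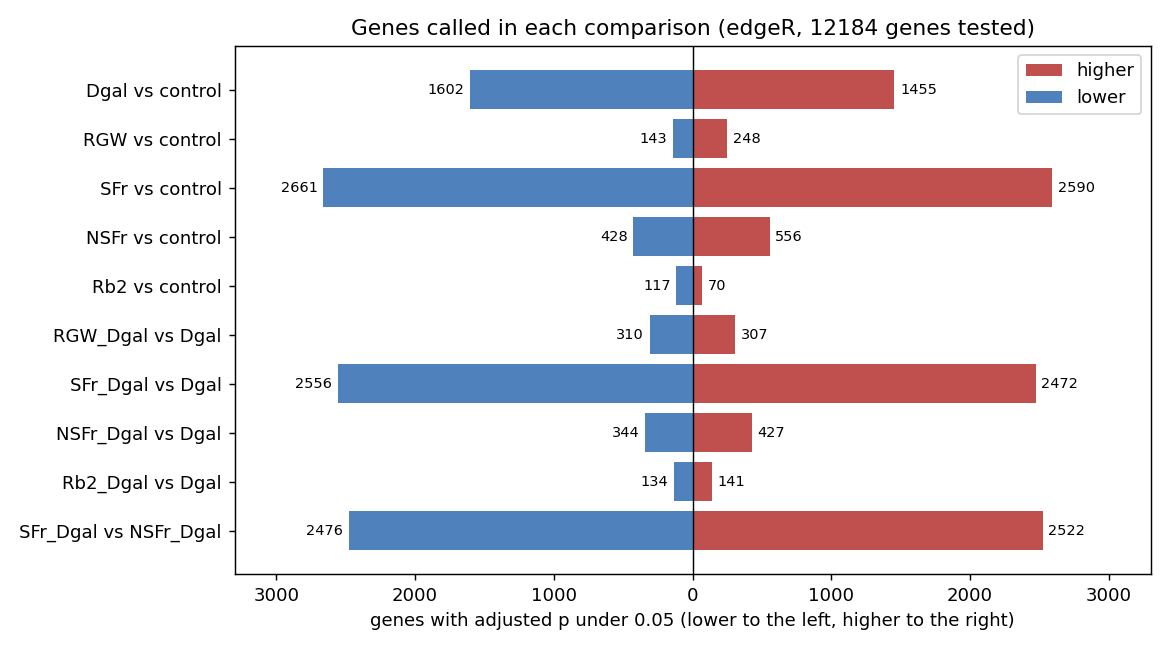
Number of genes with adjusted p under 0.05 in each comparison, with genes higher in the group named first to the right and lower genes to the left. SFr against control gave 2590 higher and 2661 lower genes, and Rb2 against control gave 70 and 117.

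To ask what D-galactose changed in these myotubes, Dgal was compared with control. Genes of cell division fell most: Ccnb2, the cyclin B2 gene (log2 fold change -1.33 ± 0.099, adjusted p = 6.43e-12), Birc5 (-1.32 ± 0.12) and Mki67, the proliferation marker (-1.32 ± 0.17, n = 3 per group). Ccna2, which encodes cyclin A2, went from 25.2 ± 0.709 CPM in control to 10.8 ± 0.986 CPM in Dgal (SD, n = 3). The largest rises were in Rgcc, a regulator of the cell cycle (1.47 ± 0.12, adjusted p = 4.22e-11), the monocarboxylate transporter family gene Slc16a6 (1.29 ± 0.086) and the arrestin family gene Arrdc3 (1.07 ± 0.058). On GRCm38, Rgcc lies at 79288756 to 79301645 on chromosome 14 and Ccnb2 at 70407692 to 70421547 on chromosome 9. In all, 3057 genes were called, 1455 higher and 1602 lower, of which 117 changed at least 2-fold.

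Within the proliferation list, 20 of 27 genes fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of -0.91 (camera adjusted p = 4.47e-17, and 0.0171 with an estimated correlation). Other large falls were in Pbk (-1.21 ± 0.12), Nuf2 (-1.20 ± 0.099), Kif11 (-1.18 ± 0.12), Top2a, the topoisomerase II alpha gene (-1.17 ± 0.097), Cdc20 (-1.15 ± 0.089) and Aspm (-1.14 ± 0.14). Among targets of the tumour suppressor p53, 14 of 24 genes rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.18e-07, and 0.00445 with an estimated correlation). They included Btg2 (0.41 ± 0.041), Aen (0.41 ± 0.042) and Zmat3 (0.40 ± 0.045), while Cdkn1a, the p21 gene, had a log2 fold change of 0.015 ± 0.038 (adjusted p = 0.81). Of 21 endoplasmic reticulum chaperone genes, 19 fell and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 4.68e-11, and 0.015 with an estimated correlation), among them Manf (-0.34 ± 0.048) and Hsp90b1 (-0.26 ± 0.038).

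Of the lists of metabolic genes, camera did not call nuclear oxidative phosphorylation (adjusted p = 0.239), fatty acid oxidation (0.502), galactose and polyol metabolism (0.918) or mitochondrial biogenesis (0.969). Among 24 glycolysis genes, 14 rose and 1 fell, including Pkm, the muscle pyruvate kinase gene (0.28 ± 0.033), Hk2, hexokinase 2 (0.33 ± 0.041), and Aldoc (0.81 ± 0.11), with camera adjusted p = 1.54e-05 and adjusted p = 0.197 with an estimated correlation. Cholesterol synthesis genes fell in 14 of 25 cases and rose in 0 (18 and 0 adjusted over the list alone), with Insig1 at -0.47 ± 0.043 (camera adjusted p = 7.17e-06, and adjusted p = 0.123 with an estimated correlation). Among 25 genes of the amino acid and integrated stress response, 12 fell and 1 rose, led by the serine synthesis gene Psat1 (-0.51 ± 0.046) and asparagine synthetase, Asns (-0.51 ± 0.058), with camera adjusted p = 7.17e-06 and adjusted p = 0.258 with an estimated correlation. Of the 13 mitochondrially encoded genes, 7 rose and 0 fell, mt-Nd6 by 0.62 ± 0.11 and mt-Nd1 by 0.94 ± 0.19 (camera adjusted p = 3.02e-05, and adjusted p = 0.153 with an estimated correlation). In smaller groups, camera called osmotic stress genes lower (4 of 11 fell, 1 rose; adjusted p = 0.0464, and 0.258 with an estimated correlation), with the taurine transporter Slc6a6 at -0.32 ± 0.047. It called fatty acid synthesis genes lower (4 of 15 fell, 1 rose; adjusted p = 0.0292, and 0.33 with an estimated correlation) and glucose-responsive genes higher (2 of 8 rose; adjusted p = 0.0292, and 0.197 with an estimated correlation).

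Muscle genes did not move as a group. Of 37 sarcomere genes, 9 rose and 6 fell (camera adjusted p = 0.894), although Myh3, the embryonic myosin heavy chain gene, fell from 4190 ± 136 to 2710 ± 114 CPM (log2 fold change -0.63 ± 0.044, adjusted p = 1.91e-12; named after its values were seen). Myog had a log2 fold change of 0.12 ± 0.047 (adjusted p = 0.0501). Of 19 atrophy genes 4 rose and 0 fell (camera adjusted p = 0.441), with the ubiquitin ligase gene Fbxo32 at 0.25 ± 0.050 and Trim63 at -0.059 ± 0.062 (adjusted p = 0.518). Genes secreted by senescent cells showed 3 rises and 4 falls among 21 (camera adjusted p = 0.902). Markers of undifferentiated myoblasts fell in 4 of 14 cases and rose in 1, Pax7 at 0.25 ± 0.061 (camera adjusted p = 0.038, and adjusted p = 0.123 with an estimated correlation). Of 7 tested bone and cartilage markers and 2 tested fat cell markers, edgeR and DESeq2 called 0, with 1 and 0 at an unadjusted p under 0.05.

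Plekhn1, the tenth largest rise (0.84 ± 0.28, adjusted p = 0.0306), did not pass without control 1, control 2, Dgal 2 or Dgal 3, and its adjusted p ranged from 0.000508 to 0.123 over the alternatives. mt-Nd1, mt-Nd5 and mt-Co1 did not pass in a fit with only these 2 groups, with adjusted p up to 0.111, from 1.41e-05 for mt-Nd1.

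**Figure D2:**
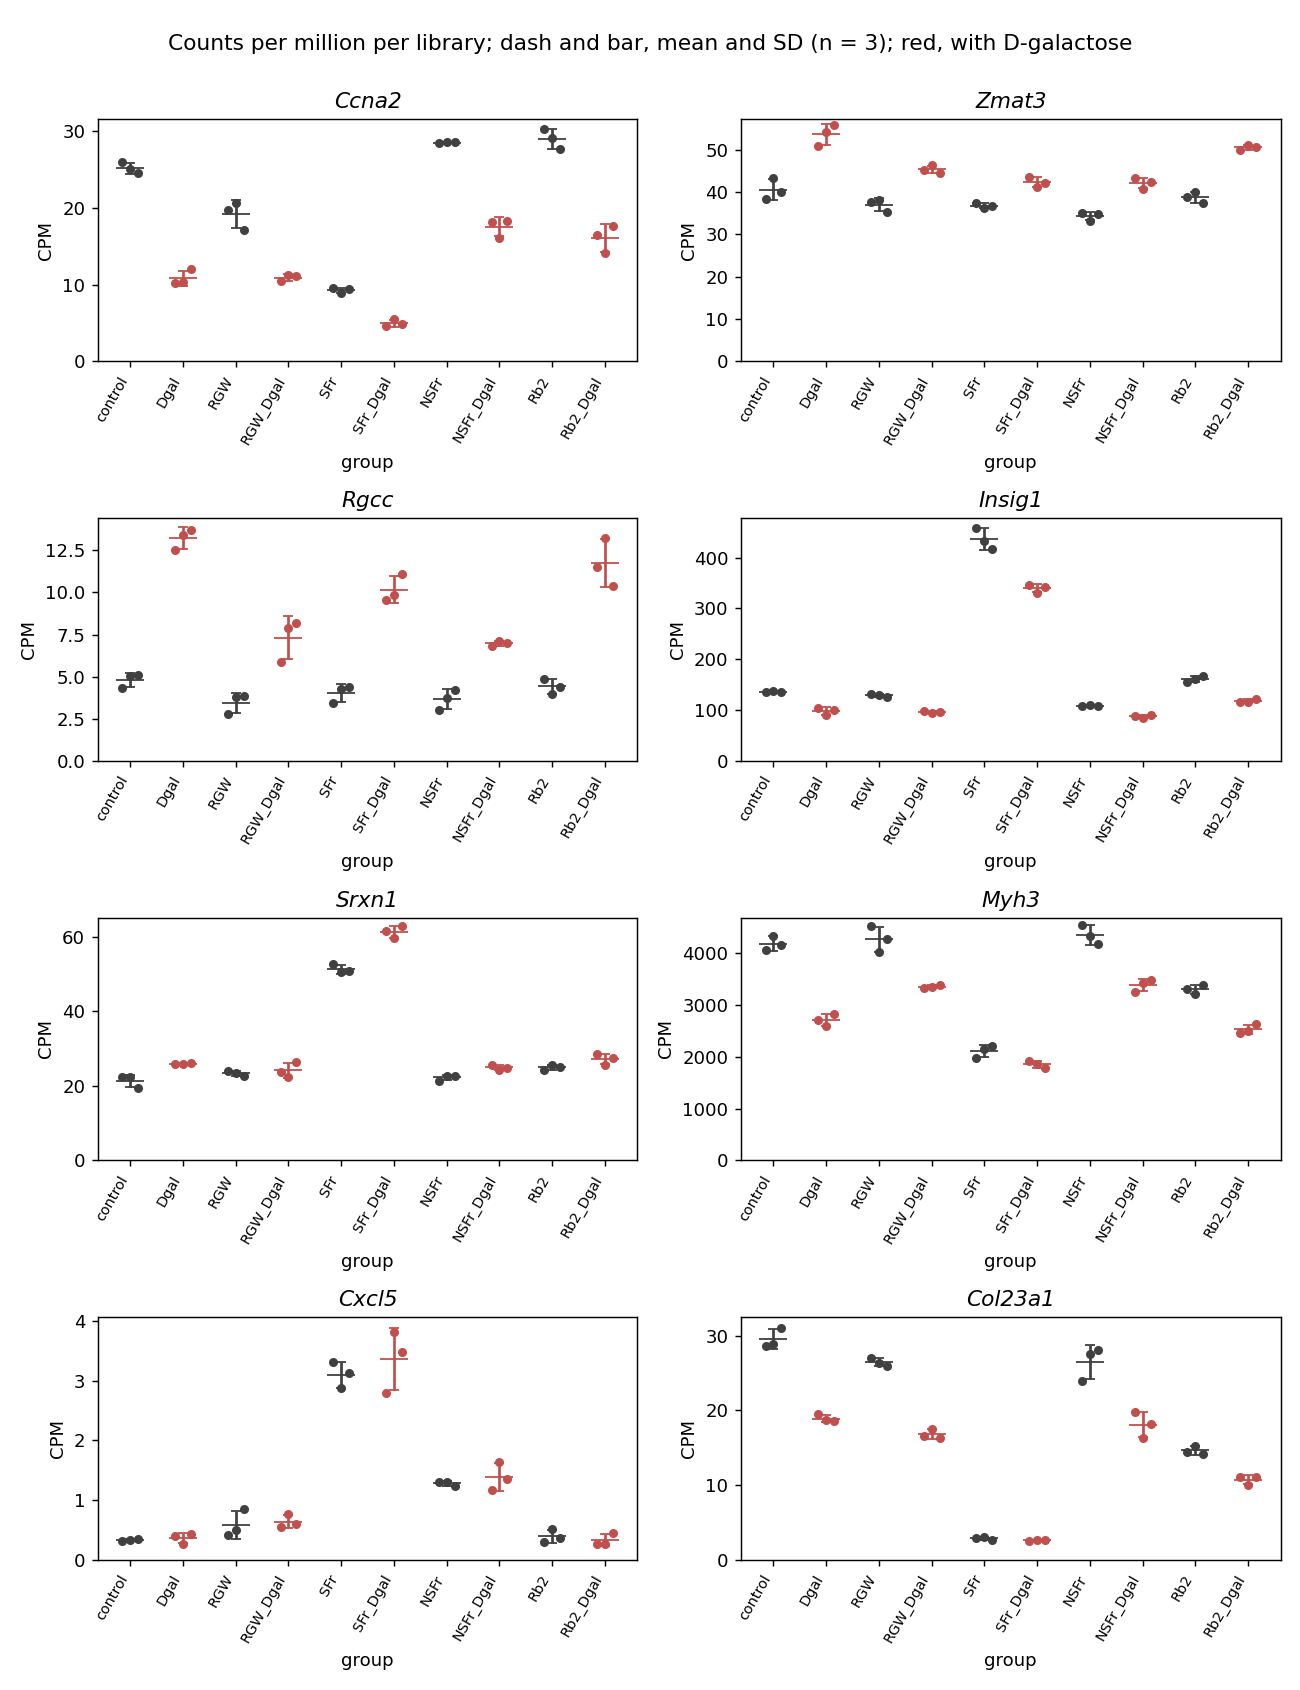
CPM of 8 named genes in each library by group (n = 3), picked for display after their values were seen; the dash and bar give the mean and SD, and red marks groups with D-galactose. Ccna2 fell with D-galactose in each background, Insig1 and Srxn1 were highest in the SFr groups, and Rgcc was 13.2 ± 0.636 CPM in Dgal and 6.98 ± 0.145 CPM in NSFr_Dgal.

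The saponin fraction alone gave the most calls against control: 5251 genes, 2590 higher and 2661 lower, with 549 changed at least 2-fold. Aldh3a1, an aldehyde dehydrogenase induced through the aryl hydrocarbon receptor, rose by 2.29 ± 0.086 on the log2 scale (adjusted p = 4.5e-21), Thbd, the thrombomodulin gene, by 2.12 ± 0.055, and Gpr137b by 2.14 ± 0.078. The collagen gene Col23a1 fell from 29.5 ± 1.35 to 2.90 ± 0.216 CPM (log2 fold change -3.35 ± 0.083, adjusted p = 5.23e-26), and Fst, which encodes the myostatin antagonist follistatin, changed by -2.20 ± 0.051. Insig1, a sterol-regulated gene at 28071363 to 28078662 on chromosome 5, rose from 137 ± 0.998 to 436 ± 21.6 CPM.

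Of 25 cholesterol synthesis genes, 24 rose and 0 fell after SFr (camera adjusted p = 1.04e-18, and 0.00185 with an estimated correlation), including Cyp51 (0.90 ± 0.036) and Hmgcs1 (0.86 ± 0.037). Antioxidant targets of NRF2 rose in 24 of 26 cases and fell in 0 (4.81e-17, and 0.00165 with an estimated correlation), with the sulfiredoxin gene Srxn1 at 1.26 ± 0.053 and Gstm1 at 1.63 ± 0.062. Sarcomere genes fell in 33 of 37 cases and rose in 0 (8.76e-21, and 0.00185 with an estimated correlation), among them Mybpc1 (-2.06 ± 0.068) and Myh3 (-0.99 ± 0.044). The transcription factor genes Mef2a (-0.90 ± 0.038) and Mef2c (-1.06 ± 0.046) were among 14 of 19 myogenic genes that fell (2 rose; camera adjusted p = 9.23e-07, and 0.0184 with an estimated correlation). Proliferation genes fell in 25 of 27 cases and 1 rose (1.23e-13, and 0.0184 with an estimated correlation), and 13 of 21 genes of senescence-associated secretion rose while 6 fell (0.000242, and 0.00218 with an estimated correlation), Igfbp4 by 1.46 ± 0.062 and Cxcl12 by 0.91 ± 0.035. Igfbp3, from the same list, changed by -1.34 ± 0.077.

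All 5 tested aryl hydrocarbon receptor targets rose after SFr (camera adjusted p = 5.21e-05, and 0.00185 with an estimated correlation). Fatty acid synthesis genes rose in 11 of 15 cases and fell in 2 (1.27e-06, and 0.0253 with an estimated correlation), with the desaturase gene Scd1 at 0.92 ± 0.035. Autophagy and lysosome genes rose in 14 of 26 cases and fell in 2 (4.23e-05, and 0.0491 with an estimated correlation), with Sqstm1 at 0.71 ± 0.035. Interferon response genes rose in 9 of 20 cases (0.00708, and 0.0184 with an estimated correlation), and galactose and polyol genes in 4 of 12 (0.0245, and 0.0491 with an estimated correlation), with the sorbitol dehydrogenase gene Sord at 0.73 ± 0.045. Calls lost with an estimated correlation were those of heat shock genes (10 of 18 rose, 2 fell; adjusted p = 0.104) and immediate early genes (11 of 17 rose, 1 fell; adjusted p = 0.0662). They also included endoplasmic reticulum chaperones (15 of 21 fell; adjusted p = 0.0865), extracellular matrix (16 of 26 fell, 4 rose; adjusted p = 0.355) and the integrated stress response (15 of 25 fell, 1 rose; adjusted p = 0.355).

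RGW alone changed 391 genes against control, 248 higher and 143 lower, with 5 at least 2-fold. The ephrin receptor gene Epha1 rose by 0.55 ± 0.051 (adjusted p = 2.95e-08) and the transcription factor gene Tcf23 by 0.59 ± 0.086, while Cdhr1, a photoreceptor cadherin gene, changed by -0.66 ± 0.077 (adjusted p = 2.59e-06). Of 25 integrated stress response genes, 15 fell and 0 rose (20 and 0 adjusted over the list alone), including Atf3 (-0.50 ± 0.11) and Chac1 (-0.48 ± 0.10), with camera adjusted p = 3.9e-15 and adjusted p = 0.111 with an estimated correlation. Cholesterol synthesis genes fell in 7 of 25 cases, Msmo1 by 0.24 ± 0.042 (camera adjusted p = 1.69e-07, and 0.111 with an estimated correlation), and 7 of 27 proliferation genes fell (8.75e-08, and 0.138 with an estimated correlation). Camera called 9 lists, and 0 of these calls held with an estimated correlation, against 7 with fry in the same direction. The count was 229 without control 1, 245 without control 2, 196 without RGW 1, 224 without RGW 3 and 91 in a fit with only the 2 groups. Trib3 (-0.50 ± 0.13), Psrc1 (-0.49 ± 0.12) and mt-Nd5 (0.62 ± 0.15) were also among the 10 genes of largest change, with adjusted p over the alternatives from 0.00267 to 0.176 for Trib3, highest without RGW 1, from 0.00382 to 0.107 for Psrc1, also highest without RGW 1, and from 0.00269 to 0.281 for mt-Nd5, highest with only the 2 groups.

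NSFr alone changed 984 genes, 556 higher and 428 lower, with 29 at least 2-fold. The neutrophil chemokine gene Cxcl5, at 90759360 to 90761624 on chromosome 5, rose from 0.332 ± 0.016 to 1.28 ± 0.0384 CPM (log2 fold change 1.94 ± 0.28, adjusted p = 2.98e-05), and Cxcl1 rose by 1.59 ± 0.33. The rise of Cxcl5 was not particular to NSFr: it was 3.1 ± 0.217 CPM after SFr and 3.37 ± 0.52 CPM in SFr_Dgal (SD, n = 3). The adenosine receptor gene Adora1 rose by 1.06 ± 0.16 and the imprinted gene Peg10 changed by -0.54 ± 0.067 (adjusted p = 3.86e-06). Of 21 genes of senescence-associated secretion 8 rose and 0 fell (camera adjusted p = 5.74e-05, and 0.0025 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 25 cases (4.82e-15, and 0.0058 with an estimated correlation), Msmo1 by 0.37 ± 0.042, and p53 targets in 8 of 24 (1.43e-06, and 0.00517 with an estimated correlation), Zmat3 by 0.24 ± 0.046. Integrated stress response genes fell in 19 of 25 cases, Asns by 0.36 ± 0.057 and Atf4, its central transcription factor, by 0.29 ± 0.047 (camera adjusted p = 1.9e-14, and adjusted p = 0.0716 with an estimated correlation). Proliferation genes rose in 4 of 27 cases and fell in 0 (camera adjusted p = 0.00106, and adjusted p = 0.474 with an estimated correlation). The count was 592 without control 2, 638 without NSFr 1, 633 without NSFr 2 and 508 in a fit with only the 2 groups. Of the 10 genes of largest change, Rgs11, Plekhn1, Col7a1, Gdf15 and Fam221b lost their calls with single libraries left out, with highest adjusted p of 0.135, 0.101, 0.0886, 0.0788 and 0.149, and Spaca6, Trib3 and Chac1 lost theirs with only the 2 groups, at 0.0716, 0.0745 and 0.0723.

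Rb2 alone changed 187 genes, 70 higher and 117 lower, with 3 at least 2-fold. Ptn, the pleiotrophin gene, rose by 0.84 ± 0.089 (adjusted p = 1.49e-07), Fbln7 by 0.70 ± 0.072 and the ferritin receptor gene Scara5 by 0.60 ± 0.079. Col23a1 fell from 29.5 ± 1.35 to 14.6 ± 0.588 CPM (log2 fold change -1.01 ± 0.064, adjusted p = 2.9e-13), and the Wnt pathway genes Sfrp2 (-0.80 ± 0.049) and Nkd2 (-0.66 ± 0.073) fell too. Camera called proliferation genes higher (median 0.090, adjusted p = 0.00577, and adjusted p = 0.604 with an estimated correlation), while edgeR and DESeq2 called 0 of its 27 members, with 7 at an unadjusted p under 0.05. It also called cholesterol synthesis genes higher (2 of 25 rose; adjusted p = 0.00577, and 0.563 with an estimated correlation), with Insig1 at 0.24 ± 0.041. The count was 115 without control 3 and 106 in a fit with only the 2 groups.

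Rb2 is a saponin, and its effects were set beside those of the saponin fraction, at doses given in different units. Of 187 genes called after Rb2 alone, 158 were also called in SFr_Dgal against Dgal, which shares no library with it, against 77.2 for independent lists, and 114 in the same direction, against 38.7. Across all genes the correlation of the log2 fold changes was 0.0594 (Pearson). Of 391 genes called after RGW alone, 294 were also called there, against 161, and 210 in the same direction, against 80.3. The difference between Rb2 and SFr alone was not tested gene by gene. Insig1 was 161 ± 6.3 CPM after Rb2 and 436 ± 21.6 CPM after SFr (SD, n = 3), and Srxn1 was 24.9 ± 0.76 and 51.3 ± 1.15 CPM.

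With D-galactose, the saponin fraction again changed most genes: SFr_Dgal differed from Dgal in 5028 genes, 2472 higher and 2556 lower. Aldh3a1 rose by 2.14 ± 0.090, Fbxo40, a muscle F-box gene, by 2.03 ± 0.062 and Insig1 by 1.79 ± 0.042 (adjusted p = 3e-26). Padi3 (-2.93 ± 0.22), Col23a1 (-2.85 ± 0.091) and Mybpc1 (-1.96 ± 0.071) fell. Of the 3696 genes called both for SFr alone and for SFr_Dgal against Dgal, 3689 moved in the same direction (r = 0.798 across genes, which are not independent replicates). Cholesterol synthesis genes rose in 24 of 25 cases (camera adjusted p = 3.62e-22, and 0.00113 with an estimated correlation), NRF2 targets in 23 of 26 with 1 lower (6.05e-18, and 0.00113 with an estimated correlation), and sarcomere genes fell in 26 of 37 (2.05e-13, and 0.0136 with an estimated correlation). Proliferation genes fell in 22 of 27 cases with 1 higher (1.66e-10, and 0.0403 with an estimated correlation), Ccna2 by 1.14 ± 0.099. The ubiquitin ligase genes Trim63 (0.77 ± 0.059) and Fbxo32 (0.44 ± 0.049) were among 9 of 19 atrophy genes that rose, with 3 lower (camera adjusted p = 0.0365, and adjusted p = 0.0519 with an estimated correlation). Cdkn1a (-0.52 ± 0.038), Myog (-0.52 ± 0.047) and Ckm, muscle creatine kinase (-0.58 ± 0.051), were lower.

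RGW_Dgal differed from Dgal in 617 genes, 307 higher and 310 lower. Rgcc went from 13.2 ± 0.636 to 7.32 ± 1.28 CPM (log2 fold change -0.85 ± 0.11, adjusted p = 4.17e-06), Slc16a6 changed by -0.63 ± 0.079 and Cdhr1 by -0.99 ± 0.078, while Enpp2, the autotaxin gene, rose by 0.67 ± 0.097. Of 24 p53 targets, 12 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 1.49e-12, and 0.000152 with an estimated correlation), Ccng1 by 0.39 ± 0.035 and Polk by 0.37 ± 0.048. Sarcomere genes rose in 6 of 37 cases, Myh3 by 0.31 ± 0.043 (camera adjusted p = 0.000455, and adjusted p = 0.334 with an estimated correlation), and cholesterol synthesis genes fell in 7 of 25 with 2 higher (0.000252, and 0.334 with an estimated correlation). The count was 342 without Dgal 3, and 348 both without RGW_Dgal 2 and in a fit with only the 2 groups. Abca1 (0.59 ± 0.15) and Tmem158 (0.58 ± 0.16), 2 of the 5 largest rises, had adjusted p from 0.000601 to 0.125 and from 0.00833 to 0.194 over the alternatives, and Tmem158 also missed the threshold with the replicate block, at 0.0574.

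NSFr_Dgal differed from Dgal in 771 genes, 427 higher and 344 lower. Ccna2 went from 10.8 ± 0.986 to 17.5 ± 1.25 CPM (log2 fold change 0.69 ± 0.081, adjusted p = 1.33e-06), against 25.2 ± 0.709 CPM in control and 28.5 ± 0.0896 CPM after NSFr alone, and the kinase gene Plk1 rose by 0.68 ± 0.12. Rgcc changed by -0.92 ± 0.11 and Txnip, a glucose-regulated inhibitor of thioredoxin, by -0.41 ± 0.047. Proliferation genes rose in 13 of 27 cases and fell in 0 (21 and 0 adjusted over the list alone; camera adjusted p = 2.35e-15, and 0.0264 with an estimated correlation), and p53 targets fell in 12 of 24 (1.5e-14, and 6.34e-05 with an estimated correlation). The chemokine genes Cxcl1 (2.22 ± 0.38), Cxcl5 (1.91 ± 0.27) and Ccl2 (1.26 ± 0.18) were among 7 of 21 secretion genes that rose (0.00121, and 0.00871 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 25 cases (1.01e-08, and 0.0435 with an estimated correlation), and the ribosomal protein genes Rps28 (0.84 ± 0.13) and Rpl38 (0.78 ± 0.16) rose. The count was 388 without Dgal 2, 353 without Dgal 3, 396 without NSFr_Dgal 1, 408 without NSFr_Dgal 2 and 396 without NSFr_Dgal 3. Slc7a11 (0.81 ± 0.20) had adjusted p from 2.72e-05 to 0.0837 over the alternatives, highest without Dgal 2, and Rps29 (0.78 ± 0.15) from 2.75e-05 to 0.074, highest with only the 2 groups.

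Rb2_Dgal differed from Dgal in 275 genes, 141 higher and 134 lower. The mitotic gene Nuf2 rose by 0.78 ± 0.10 (adjusted p = 1.07e-05), Scara5 by 0.75 ± 0.10 and Ptn by 0.72 ± 0.11. Col23a1 (-0.82 ± 0.072), Sfrp2 (-0.65 ± 0.052), Nkd2 (-0.60 ± 0.070) and Axin2, a Wnt feedback gene (-0.59 ± 0.094), fell. Proliferation genes rose in 7 of 27 cases (16 adjusted over the list alone, with 1 lower), Ccna2 by 0.56 ± 0.083 and Top2a by 0.63 ± 0.10, with camera adjusted p = 3.82e-16 and adjusted p = 0.0556 with an estimated correlation. Cholesterol synthesis genes rose in 2 of 25 cases (13 adjusted over the list alone), Insig1 by 0.26 ± 0.043, with camera adjusted p = 5.07e-10 and adjusted p = 0.0556 with an estimated correlation. The count was 126 without Dgal 2, 166 without Rb2_Dgal 1, 182 without Rb2_Dgal 2 and 161 without Rb2_Dgal 3. Col14a1 (0.83 ± 0.17) had adjusted p from 5.14e-05 to 0.0592 over the alternatives, highest without Dgal 2, and Padi3 (-0.59 ± 0.16) from 0.0116 to 0.204, not passing with any of the 6 libraries left out.

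Of the lists camera called, 3 of 11 held with an estimated correlation for Dgal, 11 of 16 for SFr, 3 of 10 for NSFr, 0 of 2 for Rb2, 1 of 5 for RGW_Dgal, 10 of 17 for SFr_Dgal, 5 of 6 for NSFr_Dgal and 0 of 7 for Rb2_Dgal.

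**Figure D3:**
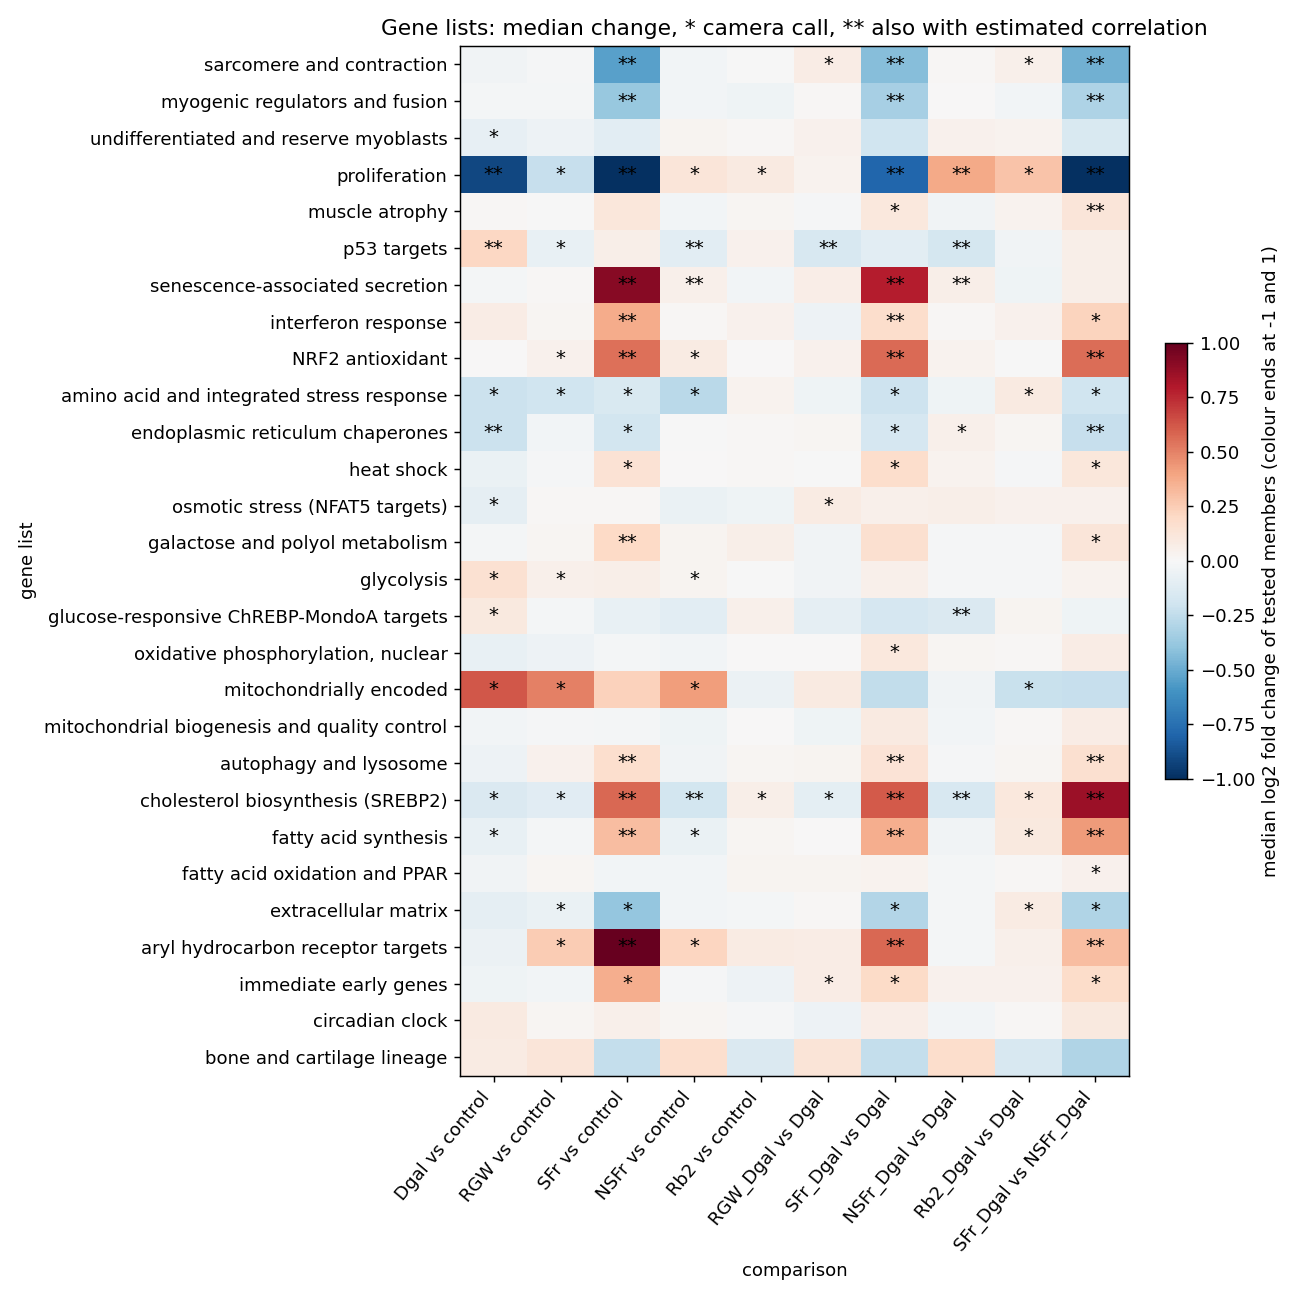
Median log2 fold change of the tested members of 28 gene lists in each comparison, on a colour scale that ends at -1 and 1; a star marks a camera adjusted p under 0.05 and 2 stars mark calls that also held with an estimated correlation. Proliferation genes had a median of -0.91 after D-galactose and of 0.38 in NSFr_Dgal against Dgal.

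The saponin and non-saponin fractions were compared directly under D-galactose. SFr_Dgal differed from NSFr_Dgal in 4998 genes, 2522 higher and 2476 lower. Insig1 was higher by 1.95 ± 0.042 (adjusted p = 1.86e-27), Gpr137b by 2.10 ± 0.080 and Thbd by 1.87 ± 0.056, and Padi3 (-3.80 ± 0.19), Gja5, the connexin 40 gene (-2.71 ± 0.073), and Hsd17b13 (-2.38 ± 0.14) were lower. Cholesterol synthesis genes were higher in 24 of 25 cases (camera adjusted p = 1.28e-23, and 0.00156 with an estimated correlation), while proliferation genes were lower in 24 of 27 with 1 higher (6.95e-16, and 0.0149 with an estimated correlation). Sarcomere genes were lower in 26 of 37 cases (3.38e-14, and 0.011 with an estimated correlation), and atrophy genes higher in 11 of 19 with 3 lower (0.0142, and 0.0247 with an estimated correlation). Over the 4 pretreated D-galactose groups, 5535 genes differed, led by Insig1 (adjusted p = 4.29e-29), Thbd and Fst.

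D-galactose was also compared with no D-galactose within each background, where it changed 1855 genes after RGW, 2315 after SFr, 1553 after NSFr and 2562 after Rb2. Among the 1455 genes that rose in vehicle-treated cells, the median log2 fold change was 0.27 in vehicle, 0.15 after RGW, 0.16 after SFr, 0.15 after NSFr and 0.20 after Rb2. Medians on the vehicle side are raised by selection, since these genes were called there. Time since the preparation may also differ between pretreated groups with and without D-galactose, as harvest times are not given. In 94.3%, 90.8%, 95.7% and 97.9% of the 3057 genes, the sign in the RGW, SFr, NSFr and Rb2 backgrounds was that in vehicle. The test of a difference in the D-galactose effect over the 5 backgrounds called 97 genes, and the single tests called 71 for SFr and 5 for NSFr. For RGW and Rb2 edgeR called 0 each, with 1153 and 546 genes at an unadjusted p under 0.05, and no other tool was run on these single tests. The 5 genes for NSFr, named after their values were seen, were the serine and asparagine synthesis genes Psat1 (0.38 ± 0.064), Phgdh (0.40 ± 0.073) and Asns (0.45 ± 0.082), with Mxd1 (0.26 ± 0.051) and Ephx1 (-0.37 ± 0.071). Asns had already fallen after NSFr alone (log2 fold change -0.365 against control), so its smaller fall with D-galactose started from a lower level. The count of 97 was 47 without SFr 1, 48 without SFr 3, 54 without SFr_Dgal 2, 52 without SFr_Dgal 3 and 170 with DESeq2.

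Of the 3057 D-galactose genes, pretreatment moved 282 in the opposite direction and 31 in the same direction in RGW_Dgal against Dgal, 385 and 33 in NSFr_Dgal, 165 and 22 in Rb2_Dgal, and 848 and 793 in SFr_Dgal. Independent lists would give 77.4 and 77.4, 97.2 and 96.2, 34.5 and 34.5, and 630 and 631. Zmat3 was 40.5 ± 2.42 CPM in control, 53.6 ± 2.54 in Dgal, 45.3 ± 0.858 in RGW_Dgal, 42.3 ± 1.13 in SFr_Dgal, 42.1 ± 1.24 in NSFr_Dgal and 50.5 ± 0.552 in Rb2_Dgal (SD, n = 3). Without D-galactose it was 37 ± 1.51 CPM after RGW, 36.8 ± 0.585 after SFr, 34.3 ± 0.995 after NSFr and 38.7 ± 1.28 after Rb2. Both comparisons use the same Dgal libraries, and 100 simulated unchanged groups, which had at most 7 called genes and so give no baseline for these counts, had a covariance of fold changes of -0.0138 (from -0.022 to -0.00922) against the observed -0.0197 for RGW, -0.00513 for SFr, -0.0244 for NSFr and -0.0254 for Rb2. The RGW covariance lay inside the simulated range, so this measure does not tell it apart from unchanged groups. The covariances of NSFr and Rb2 lay below the range and that of SFr above it. The correlation of fold changes ran from -0.345 to -0.164 in the simulations. It was -0.367 for RGW, -0.443 for NSFr and -0.472 for Rb2, all below that range, and -0.0448 for SFr, above it. For RGW the measures therefore disagree. With 3 Dgal libraries no split that keeps 2 libraries on each side was possible, and part of the excess may come from the shared libraries. Opposite counts were 159 for RGW, 535 for SFr, 164 for NSFr and 70 for Rb2 without Dgal 2, and 176 for RGW and 188 for NSFr without Dgal 3. They were 175 for RGW without RGW_Dgal 2, 214, 222 and 228 for NSFr without NSFr_Dgal 1, 2 and 3, and 105 for Rb2 without Rb2_Dgal 3. In fits with only the groups compared they were 121 for RGW, 493 for SFr, 313 for NSFr and 139 for Rb2.

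A score that uses no Dgal library was added after the data were seen: the mean log2 CPM of the 1031 genes that rose minus that of the 1284 that fell in SFr_Dgal against SFr, with control at 0. It was 0.468 ± 0.0402 in Dgal, 0.395 ± 0.0271 in RGW_Dgal, 0.326 ± 0.00344 in NSFr_Dgal and 0.354 ± 0.0116 in Rb2_Dgal (SD, n = 3). The 3 Dgal libraries scored 0.11 above the 9 libraries of these 3 pretreated groups (exact two-sided permutation p = 0.00455 over 220 splits, the smallest they can give). Taken singly, each group of 3 against Dgal gave an exact permutation p of 0.1, the smallest possible with 20 splits.

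**Figure D4:**
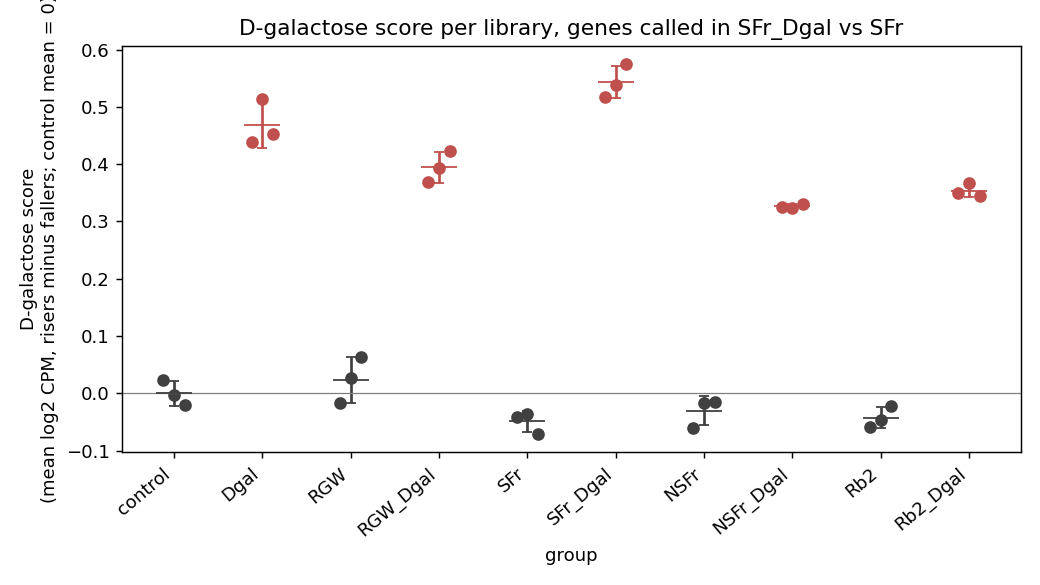
D-galactose score of each library by group (mean log2 CPM of genes that rose minus genes that fell in SFr_Dgal against SFr, control mean set to 0), with dash and bar for mean and SD (n = 3). Dgal libraries averaged 0.468 and NSFr_Dgal libraries 0.326; SFr_Dgal, at 0.544 ± 0.0284, was used to choose the genes and is not independent.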

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

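The 6 single genes below follow the rule fixed before the data were examined, and the weighing of list differences by an estimated correlation was chosen after the data were seen. The D-galactose effect differed over the 5 backgrounds in 97 genes, between vehicle and SFr in 71 and between vehicle and NSFr in 5, by interaction terms. The real grouping of the 30 libraries was the only 1 of 50 splits that gave as many genes for the 5 backgrounds, and the highest other split gave 2. These splits mix groups that differ by the effects of SFr and D-galactose themselves, so their common dispersion was 0.00915 to 0.0147 against the real 0.00181, and the bound set for this test was wrong: the splits leave open whether chance can be excluded for that count.

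Car2, the carbonic anhydrase 2 gene (interaction adjusted p = 7.27e-05 over the 5 backgrounds), and Fam167a, Mcpt8 and Asprv1 (2.24e-06 each) had their largest differences after SFr. The D-galactose effect on log2 expression was lower there than in vehicle by an interaction of -0.54 ± 0.065 for Fam167a, -0.84 ± 0.12 for Mcpt8, -0.44 ± 0.083 for Asprv1 and -0.54 ± 0.080 for Car2. The immediate early gene Egr3 (1.58e-05) and the cell cycle transcription factor gene E2f2 (2.37e-05) had interactions of -0.21 ± 0.053 and -0.34 ± 0.073 after SFr and of 0.25 ± 0.053 and 0.30 ± 0.070 after NSFr. Of these 4 single terms only that of E2f2 after SFr passed the threshold (adjusted p = 0.0183), and Egr3 after SFr (0.0586), Egr3 after NSFr (0.0589) and E2f2 after NSFr (0.0886) missed it.

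Among the fixed lists, p53 targets had a median interaction of -0.102 for RGW (camera adjusted p = 2.33e-06, and 0.0123 with an estimated correlation). Sarcomere genes had a median interaction of 0.186 for SFr (5.79e-13, and 0.0269 with an estimated correlation), and genes of senescence-associated secretion had -0.125 for SFr (0.00465, and 0.0269 with an estimated correlation). These were 3 of 36 list interactions that camera called with the preset correlation. Per the labels, preparations alone were given for 12 h and D-galactose followed for 24 h in the combinations; whether all groups were harvested at the same time is not given in the sources used here.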

How the results depend on the processing

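All 16 counts stayed within 1.5 times under RLE scaling, without the filter on low counts and with the replicate block. No link between same-numbered libraries was seen: they had a mean correlation of deviations of -0.00229, against 0.00115 for different numbers. Over 0.1 were 8 of 135 same-numbered pairs, and 10 of 30 libraries correlated best with their own number. A shared culture or day is not excluded by this, above all if numbers did not follow it across groups. With the replicate block, D-galactose against control gave 3000 genes and the interaction 95, and among named genes and lists it ended the calls of Tmem158 in RGW_Dgal (adjusted p = 0.0574), fatty acid synthesis after NSFr (0.0502) and osmotic stress in RGW_Dgal (0.055). DESeq2 gave 170 interaction genes, and the cause was not tested. A fit with only the groups compared gave 91 genes for RGW, 508 for NSFr, 106 for Rb2 and 348 for RGW_Dgal against Dgal, and 121 and 493 opposite genes for RGW and SFr, but more genes for NSFr_Dgal (1030) and Rb2_Dgal (365) against Dgal; the cause was not tested.

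With each library left out, counts ranged from 2104 to 2787 for D-galactose, 196 to 348 for RGW, 4549 to 4927 for SFr, 592 to 861 for NSFr, 115 to 209 for Rb2, 342 to 453 for RGW_Dgal, 4292 to 4742 for SFr_Dgal, 353 to 624 for NSFr_Dgal and 126 to 227 for Rb2_Dgal. They ranged from 4217 to 4854 for SFr_Dgal against NSFr_Dgal, 47 to 122 for the interaction and 4846 to 5741 for the 4 pretreatments. Opposite genes ranged from 159 to 271 for RGW, 535 to 832 for SFr, 164 to 380 for NSFr and 70 to 175 for Rb2. Lists called with an estimated correlation were 3 for D-galactose, 0 for RGW, 3 for NSFr, 0 for Rb2, 1 for RGW_Dgal, 10 for SFr_Dgal, 0 for Rb2_Dgal and 10 for SFr_Dgal against NSFr_Dgal. Fry, which tests a list without comparing it to other genes, called 26 for SFr, 1 for Rb2, 9 for RGW_Dgal, 4 for Rb2_Dgal and 26 for SFr_Dgal against NSFr_Dgal.

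Of 314 named calls, 25 were lost in at least 1 fit with a library left out and 16 with only the groups compared. Neither gene whose sign changed was called: Cdkn1a after D-galactose ranged from -0.00822 to 0.0681 with each library left out (-0.00189 without control 2, -0.00725 without Dgal 2), and Trim63 from -0.104 to 0.0156. As alternatives chosen after seeing the data, D-galactose gave 3050 genes without mitochondrially encoded genes, and NSFr_Dgal against Dgal 719 without ribosomal protein genes. Depth limits genes of low CPM: Cxcl5, at 0.332 CPM in control, had a standard error of 0.28 on the log2 scale after NSFr, against 0.078 for Ccna2, at 25.2 CPM, after D-galactose.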

Other observations

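The tests of ribosomal protein genes, of NF-kB and Wnt targets, of the D-galactose score and of the causes of lower proliferation genes were chosen after these patterns had been seen; for the proliferation tests and the comparisons of score shifts and responses the values were known too. Ribosomal protein genes, a group not among the fixed lists, fell in 56 of 78 cases and rose in 0 after D-galactose (median log2 fold change -0.245) and rose in 24 with 0 lower in NSFr_Dgal against Dgal (median 0.168). In SFr_Dgal against Dgal, 25 rose and 2 fell (median 0.118). Other genes of the same transcript length had a median of 0.0436 there, and the correlation with length over all genes was -0.166. The test of length bias below covers NSFr_Dgal only. These comparisons share the Dgal libraries, where the mean log2 level of ribosomal protein genes, relative to all libraries, was the lowest of the 10 groups (-0.172). It was -0.0682 in RGW_Dgal, -0.0398 in SFr_Dgal, 0.0401 in NSFr_Dgal and -0.108 in Rb2_Dgal, against 0.0678 in control and 0.153 after NSFr alone. This level varied between libraries of a group, with an SD of 0.118 in control and 0.162 in RGW (n = 3).

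The higher median of ribosomal protein genes in NSFr_Dgal, of which 24 of 78 were called and which were not tested as a group, was set against 2 technical explanations. Other genes of the same transcript length had a median of 0.00481, 0.0287 of the ribosomal median, which argues against length bias as the cause, although the correlation with length over all genes (-0.0371) had been seen before. Reads shared with processed pseudogenes cannot be told apart from a change in expression. The correlation of pseudogene number with the size of change was -0.0781 (Spearman, permutation p = 0.752), but 10.8% of 13132 annotated processed pseudogenes carry a parent name, so the check is void, a condition added after the correlation was seen.

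The lower proliferation genes after D-galactose were set against fewer undifferentiated cells and against depth. Markers of undifferentiated myoblasts had a median of -0.0827, above the proliferation median of -0.91 by more than their median absolute deviation of 0.132. That argues against a loss of cells carrying these markers of the size needed. A smaller loss stays open as a part: of 14 markers Heyl (-0.25), Sox9 (-0.255), Spry1 (-0.208) and Hes1 (-0.228) fell and Pax7 rose (0.248), and camera called the list lower (adjusted p = 0.038) but not with an estimated correlation (0.123). The lowest median of 1000 random lists matched on expression was -0.121, which argues against a fall shared by genes of the same abundance. Scaling holds the median log2 fold change over all genes near 0 (-0.00417). The random lists therefore could not show a general shift from depth or a few abundant genes. The undifferentiated markers leave out the proliferation genes, so a loss limited to dividing cells was not covered by this test. No other biological explanation was tested.

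The shift of D-galactose genes back towards control after RGW, NSFr and Rb2 may partly come from choosing genes on the shared Dgal libraries. For RGW the covariance of fold changes (-0.0197) lay within the range of simulated unchanged groups (-0.022 to -0.00922). The RGW correlation of fold changes (-0.367) lay below its simulated range (-0.345 to -0.164), so the simulation does not settle this for RGW. On genes chosen in other libraries the 9 pretreated libraries still scored below the 3 Dgal libraries (exact permutation p = 0.00455). That argues against the choice of genes as the whole cause for the 3 groups pooled. The 9 libraries of these preparations alone scored 0.0163 below control (exact permutation p = 0.545). This pools groups of unlike sign: RGW alone averaged 0.0238 ± 0.0401, NSFr alone -0.0305 ± 0.0252 and Rb2 alone -0.0422 ± 0.0182 (SD, n = 3). Pooled over the 3 preparations, the shift with D-galactose was larger by 0.0937 (standard error 0.0248). For the pooled groups that argues against a shift of the same size without D-galactose as the whole cause. A smaller shift of this kind stays open as a part. The same difference is the response to D-galactose in vehicle minus that after pretreatment, pooled over the 3 preparations. On this score the response was smaller after pretreatment by 3.77 standard errors, a hypothesis found and tested on the same data. Single interaction tests called 0, 5 and 0 genes for RGW, NSFr and Rb2 by edgeR, with 1153, 862 and 546 at an unadjusted p under 0.05. Per the labels, 24 h of D-galactose followed the 12 h of preparation in the combinations. Time since the preparation may therefore differ from that in the preparations alone, and its share in this difference was not tested.

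Higher chemokine genes after NSFr could reflect NF-kB activity, and a list of 28 NF-kB targets without the chemokines already seen, 6 of them also in the secretion list, was tested with 22 members. Most of those 6 encode other chemokines, so the list is not independent of the secretion list. The NF-kB list rose after NSFr alone (camera adjusted p = 0.026) and missed the threshold in NSFr_Dgal against Dgal (adjusted p = 0.366), so the test leaves NF-kB activity open. In SFr against control 15 of 22 rose and 1 fell (adjusted p = 0.00162), and in SFr_Dgal against Dgal 13 and 1 (0.0341). Nkd2 and Sfrp2 were lower after Rb2 alone and in Rb2_Dgal against Dgal, and Axin2 was named only in the latter. These falls could reflect changed Wnt signalling, but a list of 22 tested Wnt targets without these genes did not pass. Of that list Myc is also an immediate early gene. It had camera adjusted p = 0.592 after Rb2 alone and 0.764 in Rb2_Dgal against Dgal, and the list medians were -0.0749 and 0.0279.

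For each pairwise comparison the real split was 1 of 10 possible splits of its 6 libraries, too few for a share under 0.05. Against the real counts of 3057 for D-galactose, 391 for RGW, 5251 for SFr, 984 for NSFr and 187 for Rb2, the highest other splits gave 2, 2, 0, 0 and 0. Against 617 for RGW_Dgal, 5028 for SFr_Dgal, 771 for NSFr_Dgal, 275 for Rb2_Dgal and 4998 for SFr_Dgal against NSFr_Dgal they gave 0, 0, 1, 0 and 0. Among the 4 pretreated groups the real split, with 5535 genes, was the highest 1 of 50, and the highest other gave 4572. The share of the real split is under the 0.05 set for this test and is the smallest these splits can give. The split with 4572 was the only other drawn that kept all 3 SFr_Dgal libraries together. The 30 splits with 2 of them together had a median of 38.5, so the count follows the difference between SFr_Dgal and the other groups. Whether RGW_Dgal, NSFr_Dgal and Rb2_Dgal differ among each other is not told by these splits.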
